A study of Zea mays with 12 samples.

How the data were processed

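Transcript abundance was measured by RNA-seq in developing maize seeds collected 7 and 14 days after pollination (DAP) from wild-type plants and from *zmmsh7-2* plants, which the labels describe as an MSH7 knockout. There were 4 groups of 3 libraries, 12 in all. Per the labels' protocols, total RNA was treated with DNase and made into libraries with the NEBNext Ultra II RNA kit. Whether ribosomal RNA was removed, polyadenylated RNA was selected or strand was kept is not given in the sources used here. The values are whole-number read counts per gene, deposited by the authors in a table for each stage, without normalization. Per the submitters' processing notes, Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 1.6.4, StringTie 1.3.6 and DESeq2 were used with the genome build B73 RefGen_v4. How reads that align to several places were counted, and the annotation release, are not given in the sources used here.

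Each library was assigned to its genotype and stage by matching the column name, with upper and lower case kept, to the sample's description. Both tables listed 46430 identifiers, of which 44146 were nuclear gene models, 365 were organelle genes, 154 were microRNA precursors and 1765 were others. The reference table of gene names used here, of the assembly Zm-B73-REFERENCE-NAM-5.0, gave symbols for 365 organelle identifiers and 153 microRNA precursors and for 0 of the nuclear gene models. Since its build differs from that of the counts, it was used for names and, for the named microRNA precursors only, for their order along the chromosomes, and no coordinates are given. The 29 lists of nuclear genes fixed before the data were examined, and the planned test of genes near MSH7, were therefore not run, and MSH7 itself was not analysed here. In their place 10 lists of organelle and microRNA genes were written from the symbols, after the identifiers had been seen and before their values.

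Differential abundance was tested in R 4.3.3 with edgeR 4.0.16, by its quasi-likelihood test on the deposited counts, with TMM normalization, its default filter on low counts by group and robust dispersion estimates. Genotypes were compared within each stage in a fit of 6 libraries. The change from 7 to 14 DAP in each genotype, and the difference between the genotype effects at the 2 stages, came from a fit of all 12 libraries. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, and adjusted p-values of single genes are from this test. Values per library are CPM scaled by the TMM factors of the stage, and log2 fold changes are given with approximate standard errors (SE). Each SE is the absolute log2 fold change divided by the square root of the F statistic of the test. Lists with at least 3 tested members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and also with an estimated correlation and with fry. The overlap between stages was tested with a two-sided Fisher's exact test among genes tested at both.

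Named genes followed a rule fixed before the data were examined. For each stage it took, among called genes with a described name, a mean of at least 1 CPM and no overlap between the replicates of the genotypes, up to 6 with the largest change in each direction. It added up to 3 called members of each list with at least 3 called members. For the difference between stages it took up to 5 described genes in each direction by adjusted p. Because nuclear gene models had no names, 4 nuclear identifiers were added after values had been seen, 2 higher and 2 lower. These had the largest changes shared by both stages among identifiers that met the same limits on abundance and overlap. Where a group had 0 counts, a lower bound on the fold was computed against a floor of 3 counts per library. Ratios that rest on few counts are given with a 95% counting interval (exact Poisson, counts summed over the 3 libraries). Floors and these intervals cover counting error only.

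Library totals ranged from 16854595 to 21932590 counts. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom between 1.66 and 2.38, so no library was treated as a duplicate. Simulated counts with 200 genes changed by known folds were used to test the fits. For genotype at 7 DAP, with 23821 genes tested, 59.6% of genes changed 1.2-fold, 73.1% of those changed 1.5-fold, 90% of those changed 2-fold and 97.8% of those changed 4-fold were recovered. For genotype at 14 DAP, with 23524 genes, the shares were 46.2%, 73.1%, 84% and 100% in the same order. For the difference between stages, with 24885 genes, they were 10.5%, 52.3%, 84.3% and 95.8%. False calls were at most 0.0689% of unchanged genes in these simulations. Only 200 genes were changed there, far fewer than were called in the data. The cutoff of the adjusted p depends on that share, so recovery and false calls in the data can differ from these rates.

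Alternatives fixed in advance were RLE factors, library totals without composition factors, no count filter, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, a fold limit of 2, leaving out the 20 most abundant genes, a replicate block, leaving out each library in turn and, for the genotype comparisons, a fit of all 12 libraries. Others were added after seeing the data and are named as such.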

Results

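Developing maize seeds of wild type and of the *zmmsh7-2* mutant were profiled by RNA-seq at 7 and 14 DAP, with 3 libraries in each of the 4 groups. MSH7 is a plant MutS homolog that acts in DNA mismatch repair, and the series is concerned with pollen fertility and grain yield. Total counts per library lay between 19741682 and 20865544 in wild type at 7 DAP, between 17502108 and 20441974 in the mutant at 7 DAP, between 20066289 and 21932590 in wild type at 14 DAP and between 16854595 and 20575609 in the mutant at 14 DAP. Pearson correlations of log2 CPM across genes were at least 0.989 within groups, at most 0.953 between genotypes of a stage and at most 0.852 between stages. The first principal component held 71.7% of the variance and separated the stages, and the second held 17.3% and separated the genotypes. The labels do not say that replicates came from separate plants or ears, so p-values measure only the spread between these libraries, which may be technical. That spread was small, with a biological coefficient of variation of 2.92% at 7 DAP and 3.28% at 14 DAP, so that changes well below 2-fold passed the test.

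Which seed transcripts differed between mutant and wild type at 7 DAP was asked first. The most abundant organelle transcript, rrn26 (ZeamMr002), the large-subunit ribosomal RNA of the mitochondrion, was lower in the mutant, at 123 ± 4.09 CPM against 186 ± 2.94 CPM in wild type (SD, n = 3 each; log2 fold change −0.60, SE 0.03, edgeR adjusted p = 5.38e-35). The small-subunit ribosomal RNA rrn18 (ZeamMr004) was at 20.5 ± 1.31 CPM in the mutant and 24.1 ± 2.73 CPM in wild type (log2 fold change −0.24, SE 0.07, edgeR adjusted p = 0.00285). The replicates of the genotypes overlapped for rrn18, and the call was lost without wild-type replicate 3 (log2 fold change −0.18). Among nuclear gene models, Zm00001d023265 had 0 counts in the 3 wild-type libraries and 882 counts in the 3 mutant libraries, or 14.9 ± 0.24 CPM. Against the floor of 3 counts per library this was at least 99.4-fold higher. Zm00001d044183 was 10.7-fold higher (95% counting interval 8.12 to 14.5), at 9.66 ± 0.08 CPM against 0.90 ± 0.25 CPM. Zm00001d021279 was 24.8-fold lower (95% counting interval 12.9 to 60.6), at 0.13 ± 0.05 CPM against 3.50 ± 0.33 CPM, and Zm00001d025409 was 25.9-fold lower (13.5 to 63.5), at 0.13 ± 0.12 CPM against 3.66 ± 0.34 CPM (SD, n = 3 each). The mutant values of these last identifiers rest on 8 counts each over 3 libraries. The log2 fold change of Zm00001d025409 moved from −4.70 to −5.44 without mutant replicate 1 and to −4.19 without mutant replicate 2. The 4 identifiers were chosen after their values were seen, and their products are not given in the sources used here.

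Of 24096 genes tested at 7 DAP, 8558 were higher and 8579 lower in the mutant, together 71.1%. With library totals as the only scaling, 9558 were higher and 7694 lower. Most of these changes were small, with a median absolute log2 fold change of 0.53 among called genes. Beyond 2-fold, 1505 genes were higher and 2077 lower, and beyond 8-fold 64 were higher and 159 lower. Called changes beyond 2-fold were more frequent among scarce transcripts, where small changes pass the test less often and estimates are noisier. With the tested genes ranked by abundance in 4 equal groups of 6024, the least abundant group held 860 of the genes higher by more than 2-fold and 928 of those lower by more than 2-fold, against 114 and 293 in the most abundant group. Organelle transcripts made up a smaller share of counts in the mutant, 0.0157% ± 0.0003 against 0.0216% ± 0.0005 (SD, n = 3 each; two-sided exact permutation test p = 0.1, the smallest p that 3 against 3 libraries allow). The mitochondrial rrn18 and rrn26 carried this fall, since without them organelle genes summed to 575 counts in wild type and 589 in the mutant, or 9.58 ± 0.10 and 10.1 ± 2.04 CPM (SD, n = 3 each; two-sided exact permutation test p = 1). At 14 DAP the order was the opposite, 0.0234% ± 0.0005 in the mutant against 0.0216% ± 0.0006 in wild type (SD, n = 3 each; two-sided exact permutation test p = 0.1), but with TMM factors the sums were close, 227 ± 5.33 and 223 ± 5.37 CPM (p = 0.5 in the same test). Of 9 organelle genes tested at 7 DAP, 0 were higher, 3 were lower and 6 were not called, counted over all genes tested and also when adjusted over the list alone. DESeq2 tested 25, of which 1 was higher and 3 lower, and with no filter 72 were tested, of which 2 were higher and 4 lower. With library totals only, 1 was higher and 3 lower. The stricter filter tested 3, of which 0 were higher and 2 lower.

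At 14 DAP the same question gave a different picture for organelle transcripts. Of 16 organelle genes tested, 13 were higher in the mutant and 1 was lower, over all genes tested and also when adjusted over the list alone, with a median log2 fold change of 1.43. Of these 16 genes, 12 passed the count filter through the mutant libraries alone, so the change itself helped to decide which were tested. With a stricter filter 6 were tested, of which 4 were higher and 1 lower, and DESeq2 tested 44, of which 13 were higher and 1 lower. Summed over all organelle genes but the mitochondrial rrn18 and rrn26, with no filter, there were 690 counts in wild type and 1911 in the mutant, or 11.4 ± 0.74 and 32.4 ± 0.16 CPM (SD, n = 3 each; two-sided exact permutation test p = 0.1). The plastid gene matK (ZemaCp003), which encodes an intron maturase, rose 3.97-fold, from 2.05 ± 0.55 CPM in wild type to 8.20 ± 0.66 CPM in the mutant (SD, n = 3 each; log2 fold change 1.99, SE 0.16, edgeR adjusted p = 3.23e-20). At 7 DAP matK was under the count filter, with a similar ratio of 3.97 from 11 counts in wild type and 43 in the mutant (95% counting interval 2.01 to 8.54) and replicates of the genotypes that overlapped, so its rise cannot be taken as particular to 14 DAP. Mitochondrial rrn18 rose from 18.1 ± 0.68 to 28.3 ± 0.36 CPM (SD, n = 3 each; log2 fold change 0.64, SE 0.07, edgeR adjusted p = 3.41e-14). In contrast, rrn26 was again lower in the mutant, at 166 ± 5.73 CPM against 194 ± 4.80 CPM (SD, n = 3 each; log2 fold change −0.22, SE 0.03, edgeR adjusted p = 2.57e-09). The reading frame orf105-c (ZeamMp073), of no assigned function, rose from 0.61 ± 0.13 to 2.97 ± 0.37 CPM (SD, n = 3 each; log2 fold change 2.26, SE 0.28).

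Of the 20 genes in the list of mitochondrial respiratory chain and cytochrome c maturation genes, 4 were tested at 14 DAP, all 4 through the mutant libraries alone, and all 4 were higher. Over all 20, with no filter, there were 121 counts in wild type and 375 in the mutant. They included cox3 (ZeamMp161) and cox1 (ZeamMp136), which encode subunits of cytochrome c oxidase, with log2 fold changes of 2.65 (SE 0.38) and 1.15 (SE 0.38), and nad4 (ZeamMp032), a subunit of respiratory complex I, with 1.73 (SE 0.48). These transcripts were scarce, with 16 counts of cox3 in the 3 wild-type libraries and 100 in the 3 mutant libraries. The call of cox1 was lost without wild-type replicate 1 (log2 fold change 0.85). Of 126 mitochondrial reading frames of no assigned function 5 were tested and 3 were higher, orf105-c, orf147-b (ZeamMp137) and orf140-b (ZeamMp094). orf147-b was 4.58-fold higher (95% counting interval 2.17 to 11.8), from 8 to 37 counts over 3 libraries. Its log2 fold change was 2.99 without wild-type replicate 3 and 1.66 without wild-type replicate 2. orf140-b was 2.48-fold higher (95% counting interval 1.37 to 4.79), from 16 to 39 counts. The call of orf140-b was lost with DESeq2 (log2 fold change 1.34), without wild-type replicate 2 (1.05) and without mutant replicate 1 (1.11). Of the 46 plastid ribosomal and transfer RNA genes 2 were tested and both were higher, and so were the 1 tested of 12 plastid NAD(P)H dehydrogenase genes, the 1 tested of 32 plastid gene expression genes and the 1 tested of 11 mitochondrial ribosomal protein and maturase genes. The 33 mitochondrial ribosomal and transfer RNA genes had 2 tested members, rrn18 and rrn26. The 22 plastid photosystem genes, the 13 genes of plastid Rubisco, cytochrome and ATP synthase and the 153 microRNA precursors had 0 tested members at either stage. The tests of whole lists cover only genes past the filter, so they share its selection. As a set the 16 organelle genes were higher relative to other genes with camera (adjusted p = 0.00551), a call that did not hold with an estimated correlation (adjusted p = 0.0957 with an estimated correlation). The respiratory list (camera adjusted p = 0.081, and adjusted p = 0.175 with an estimated correlation) and the list of reading frames (the same adjusted p-values) did not pass that test. The directional test of fry, which does not compare a list with other genes, gave adjusted p = 8.95e-05 for all organelle genes, 2.82e-05 for the respiratory list and 0.00168 for the reading frames. At 7 DAP neither the 9 organelle genes (camera adjusted p = 0.762) nor the reading frames (the same adjusted p) passed with camera. With fry the organelle genes were called (adjusted p = 0.00778) and the reading frames were not (adjusted p = 0.363). The direction found by fry was not recorded, and the median log2 fold change of the 9 genes was 0.03. Nuclear copies of organelle DNA can share reads with these genes, and how such reads were counted is not given in the sources used here.

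Over all genes at 14 DAP, 23811 were tested, 7557 were higher and 7642 lower in the mutant, together 63.8%. Beyond 2-fold, 1064 were higher and 2145 lower, and beyond 8-fold 48 were higher and 210 lower. With library totals as the only scaling, 9532 genes were higher and 6389 lower, so the near-even split at either stage depended on the composition factor. The 4 nuclear identifiers again differed. Zm00001d023265 had 0 counts in the 3 wild-type libraries and 2807 in the 3 mutant libraries, or 47.7 ± 0.94 CPM (SD, n = 3), at least 320-fold higher. Zm00001d044183 was 11.1-fold higher (95% counting interval 7.97 to 16.1). Zm00001d021279 was 33.0-fold lower, with 5 counts in the mutant against 182 in wild type (95% counting interval 14.9 to 111). Its log2 fold change moved from −5.04 to −5.69 without mutant replicate 3 and to −4.74 without mutant replicate 2. Zm00001d025409 was 23.7-fold lower (95% counting interval 14.7 to 42.8), at 0.28 ± 0.12 CPM against 6.58 ± 0.49 CPM (SD, n = 3 each).

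**Figure D1:**
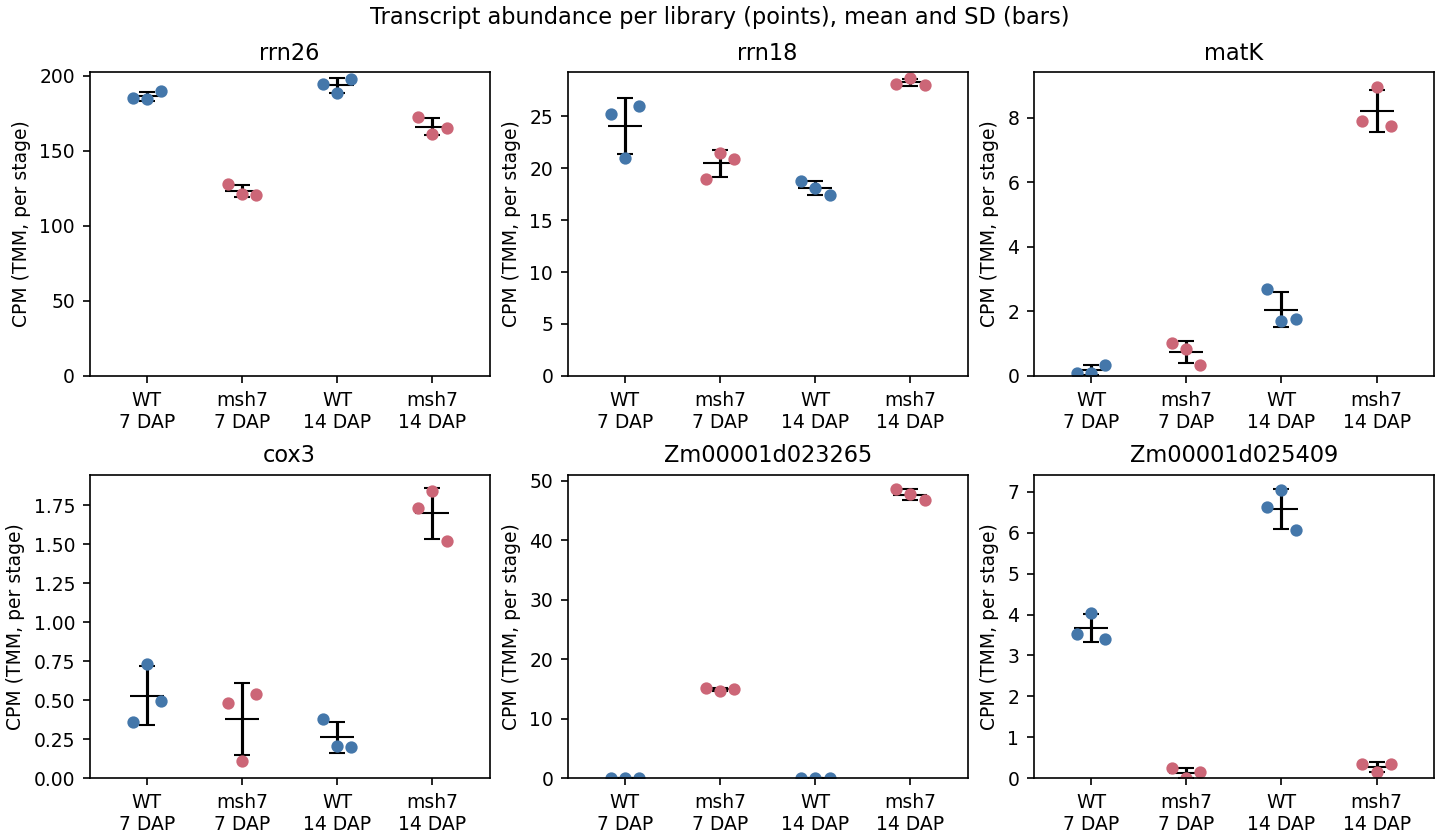
Abundance in CPM (linear axes from 0) of 4 organelle genes and 2 nuclear identifiers in the 4 groups. CPM were scaled by the TMM factors of each stage separately, so heights can be compared between genotypes of a stage but not between stages. Points are the 3 libraries of a group, and bars are the mean and SD. rrn26 was lower in the mutant at both stages, matK and cox3 were higher in the mutant than in wild type at 14 DAP, and Zm00001d023265 was at 0 in the 6 wild-type libraries.

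The most abundant transcripts took a smaller part of the mutant libraries at 14 DAP. The 20 most abundant transcripts of each library held 12.1% ± 0.11 of counts in the mutant and 14.3% ± 0.26 in wild type (SD, n = 3 each; two-sided exact permutation test p = 0.1, the smallest p possible). At 7 DAP the order was the opposite, 6.14% ± 0.004 in the mutant and 5.53% ± 0.10 in wild type (SD, n = 3 each; two-sided exact permutation test p = 0.1). Of the 100 most abundant transcripts at 14 DAP, 29 were higher, 56 were lower and 15 were not called, and 1 changed by more than 2-fold. With library totals only, 41 were higher and 45 lower. At 7 DAP, 48 were higher and 42 lower.

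**Figure D2:**
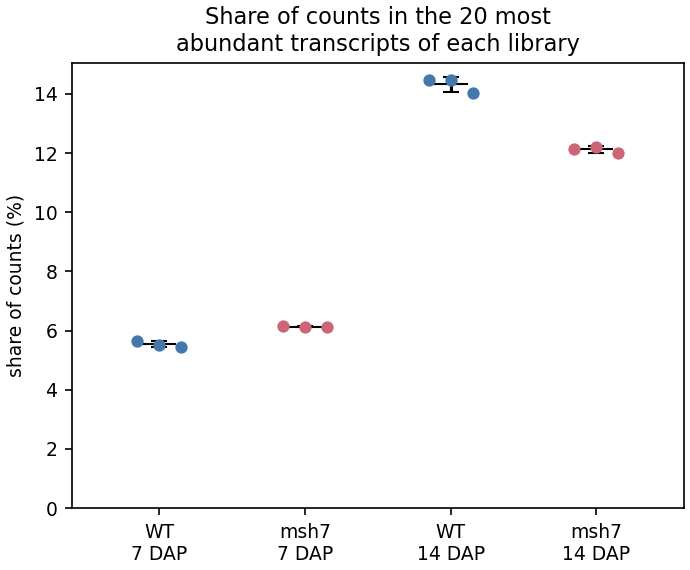
Share of each library's counts (percent) taken by its 20 most abundant transcripts, for the 4 groups. Points are the 3 libraries of a group, and bars are the mean and SD. Mutant libraries lay above wild type at 7 DAP and below it at 14 DAP.

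Whether the same genes differed at both stages was tested in comparisons that share no library. Among 22742 genes tested at both stages, 4733 were higher in the mutant at both, against 2668 for independent lists of the same lengths (odds ratio 6.10), and 4923 were lower at both, against 2615 (odds ratio 7.87). The p-values of both Fisher's exact tests were too small for the software to represent. These tests treat genes as independent and as equally likely to be called. Abundant genes were called more often, at 7 DAP 2408 higher and 2687 lower in the most abundant of 4 equal groups, against 1650 and 1558 in the least abundant. Part of the excess overlap can therefore come from abundance shared by the stages. Of the 11463 genes called at both stages, 9656 had the same direction, 84.2%, and 1807 had opposite directions. Beyond 2-fold at both stages, 390 genes were higher and 829 lower, and 55 had opposite directions. The log2 fold changes of the 2 stages had a Pearson correlation of 0.586 across genes, which are not independent replicates. Of the named organelle genes, rrn26 was lower at both stages.

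**Figure D3:**
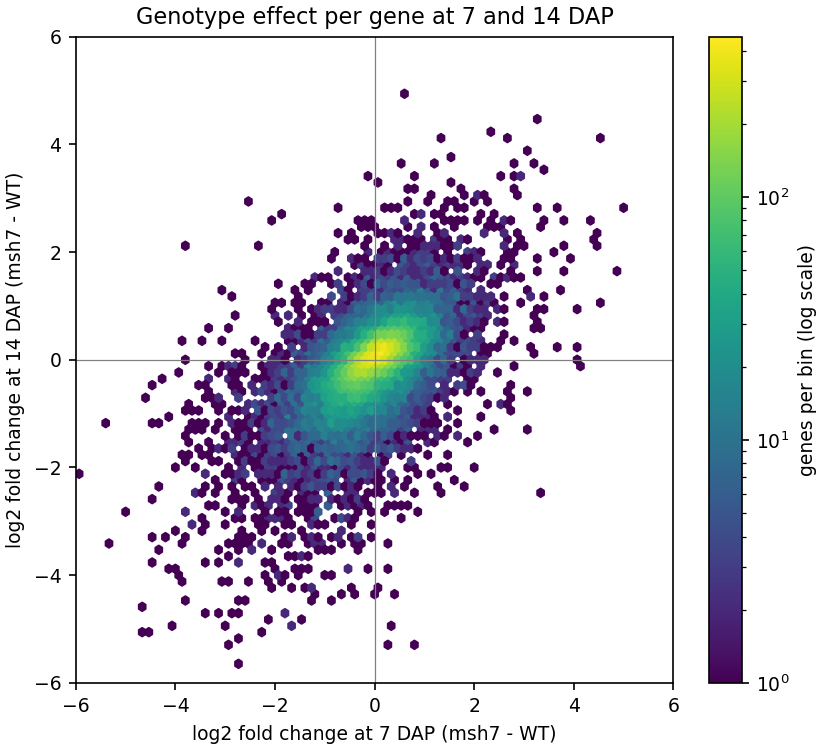
Log2 fold change (mutant minus wild type) of each gene at 7 DAP (horizontal axis) and at 14 DAP (vertical axis), as the number of genes per hexagon on a log colour scale. Of the genes tested at both stages 22732 are plotted and 10 lie outside the axes, and most large changes fall in the quadrants of equal sign.

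The genotype effect nevertheless differed in size or direction between the stages for many genes. In the test of the difference, 11873 of 25344 genes were called, 5784 with a higher value at 14 DAP and 6089 with a lower one. With library totals only the balance was the other way, 6320 higher and 5657 lower. Mitochondrial rrn18 was lower in the mutant at 7 DAP and higher at 14 DAP, a difference of 0.88 on the log2 scale (SE 0.10, edgeR adjusted p = 6.05e-13). For rrn26, lower in the mutant at both stages, the difference was 0.37 (SE 0.04, edgeR adjusted p = 3.71e-12). cox3 differed by 3.11 (SE 0.64, edgeR adjusted p = 1.85e-05), orf147-b by 3.34 (SE 0.85, edgeR adjusted p = 0.000553) and orf105-c by 1.88 (SE 0.52, edgeR adjusted p = 0.00149). At 14 DAP, leaving out wild-type replicate 3 gave 4.15 for orf147-b, and leaving out wild-type replicate 2 gave 2.80. The call of orf105-c was lost without wild-type replicate 1 at 7 DAP (1.40). No described gene was called with a lower effect at 14 DAP, since 7 of the 17 organelle genes tested had a higher one and 0 a lower one. Of the 16 tested in the fit of 14 DAP, 12 passed the count filter through the mutant libraries alone. Such a filter favours a higher effect at 14 DAP, so this split gives no independent evidence. In the fit of 7 DAP, cox3 and orf147-b were under the filter. Among the genes tested at both stages, 1807 called genes had opposite directions, 4355 had the same direction with unequal size, 3179 were called at 7 DAP only, 1988 at 14 DAP only and 111 at neither stage alone.

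The change from 7 to 14 DAP was larger than the effect of genotype in either background. In wild type 10332 genes rose and 10077 fell, of which 4573 and 4359 changed by more than 2-fold. In the mutant 9948 rose and 10025 fell, of which 4055 and 4341 changed by more than 2-fold. With library totals only, 7480 rose and 13242 fell in wild type and 7202 rose and 13182 fell in the mutant, with the median of all genes at −0.30 in both. Plastid matK rose with a log2 fold change of 3.75 (SE 0.37) in wild type and 3.79 (SE 0.23) in the mutant, and Zm00001d023265 rose with 1.98 (SE 0.07) in the mutant. Of 17 organelle genes tested in wild type, 4 rose and 0 fell. Stage coincides with the table the counts came from, so a batch between the tables cannot be told apart from stage.

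Whether mutant seeds resembled older or younger seeds was asked by comparing signs. At 7 DAP 61.0% of the 16426 called genes differed in the direction in which wild-type transcripts changed from 7 to 14 DAP, against 51.7% for simulated libraries with no genotype effect, and 62.3% with DESeq2. At 14 DAP the share was 50.2% of 14626 called genes, against 48.2% in the simulation, and with DESeq2 it was 48.7%, on the other side of 50%. The stage effect shares wild-type libraries with the genotype effects, and the simulated shares cover all tested genes. All simulated values also rest on library totals without composition factors, while the main values in the data rest on TMM factors. A real difference confined to the shared group also drives both effects, which a simulation with no genotype effect leaves out. The simulated shares are therefore no full reference, and whether mutant seeds were older or younger is not decided by them. With the stage effect of the mutant, a reference chosen after seeing the data, the shares were 50.5% and 57.6%, against 48.1% and 51.7% in the simulation. With the average of both stage effects they were 56.4% and 53.7%, against 49.9% at 7 DAP in the simulation. Across genes the correlation with the averaged stage effect was 0.06 at 7 DAP and 0.03 at 14 DAP, with covariances of 0.056 and 0.027 against −0.00058 and 0.00088 in the simulation.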

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

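The test of organelle share and the exchange of genotypes at 14 DAP were chosen after the result was seen, and the relabelling of libraries was planned before. A difference between the stages in the effect of genotype drew attention to the results given here. It was called for 11873 genes in the test of the difference itself. In 100 relabellings of genotype within stages, the real one included, 1 gave as many calls, the real one, and the highest of the others gave 8257. This does not decide whether chance can be excluded, since mixing genotypes also breaks up the effect of genotype shared by the stages (0 calls in all 77 that mixed them at both stages, 1752 to 8257 in the 22 that mixed them at 1), and exchanging the genotypes whole at 14 DAP, which was not among the 100, gave 18118.

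Among described genes the difference, 14 minus 7 DAP on the log2 scale, was 0.37 for rrn26, 0.88 for rrn18, 1.88 for orf105-c, 3.11 for cox3, 1.82 for nad4, 1.78 for cox1 and 3.34 for orf147-b. In the fit of 7 DAP, cox3, nad4 and orf147-b were under the count filter. Genes that pass it through the mutant at 14 DAP are favoured to show a higher effect there. The calls of orf105-c without wild-type replicate 1 at 7 DAP (1.40) and of cox1 without mutant replicate 3 at 7 DAP (1.39) were lost. That of nad4 was lost with DESeq2 (1.83), without a count filter (1.82) and without any of 8 libraries left out in turn, with values between 1.41 and 1.84. Without mutant replicate 2 at 7 DAP the nad4 difference was 2.93, still called. That of orf147-b was 4.15 without wild-type replicate 3 at 14 DAP and 2.80 without wild-type replicate 2 at 14 DAP, both still called.

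For the organelle transcripts at 14 DAP a candidate explanation is a larger share of organelle RNA in the mutant libraries, which would move the transcripts of an organelle alike. Both ribosomal RNAs of the mitochondrion moved apart, with a log2 fold change of rrn18 that was 0.87 above that of rrn26 (SE 0.08, with both genes taken as independent though measured in the same libraries). This argues against a larger share of mitochondrial RNA as the whole cause. It does not cover plastid transcripts, for which a larger share of plastid RNA stays open. Reads shared with nuclear copies of organelle DNA, a difference in how RNA without a poly(A) tail entered the libraries, and an effect of genotype on organelle transcripts stay open, since no value here decides between them.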

How the results depend on the processing

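The mutant as a source of the stage reference, the average reference and all settings for organelle counts were chosen after seeing the data. The counts of called genes stayed within 1.5 times of the reported values under every alternative run except a fold limit of 2, which by its construction left 3582 genes for genotype at 7 DAP, 3209 at 14 DAP, 2827 for the difference between stages, 8932 for stage in wild type and 8396 for stage in the mutant. DESeq2 called 15329, 13064, 10149, 20131 and 19618 genes in the same order. Leaving out each library in turn gave 16301 to 16702 genes for genotype at 7 DAP and 14298 to 14840 at 14 DAP. Without composition factors, 16252 of the 17137 genes called at 7 DAP and 13946 of the 15199 called at 14 DAP were called again, all with the same sign. For the shared genes of both stages DESeq2 gave 7961. The share of called genes with the sign of the stage effect moved with DESeq2 to 62.3% at 7 DAP and to 48.7% at 14 DAP, on the other side of 50%. With the stage effect of the mutant it was 50.5% and 57.6%, and with the average of both genotypes 56.4% and 53.7%. The wild-type and mutant references share different libraries with the genotype effects, and that alone can make these shares differ. No other cause was tested. Among the alternatives for single named genes, 401 values kept direction and side of the threshold, 17 lost the call and 0 reversed. These counts cover only settings in which the gene was tested, and genes not called in the main fit that stayed so count as kept. At 14 DAP nad4, cox1, orf147-b and orf140-b were not tested under the stricter filter. Of organelle genes at 7 DAP, 6 were called without a filter (2 higher and 4 lower), 5 in the fit of all 12 libraries and 1 beyond 2-fold. At 14 DAP 5 were called under the stricter filter, which tests fewer genes.

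Replicate numbers did not pair the libraries. The correlations of same-numbered deviations were at most 0.045, and not every library correlated best with its own number. With a replicate block 17130, 15235, 11884, 20405 and 19952 genes were called and 9686 were shared by both stages. The lists of nuclear genes and the region around MSH7, with their alternatives, were not run, for want of names and positions. At this depth 9 of 365 organelle genes at 7 DAP and 16 at 14 DAP, and 0 of 154 microRNA precursors at either stage, had enough counts to be tested.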

Other observations

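Of the tests given here, the relabelling of libraries and the test of scaling were written before their results, and the others were chosen after the results were seen. Genes that rose strongly during seed development were more often lower in the mutant. Of 873 genes that rose more than 8-fold from 7 to 14 DAP, by the stage effect averaged over both genotypes, 380 were lower in the mutant at 14 DAP, 183 were higher and 310 were not called, with a median log2 fold change of −0.20. Among all other genes 7262 were lower and 7374 higher (two-sided Fisher's exact test, p = 5.78e-17, with genes that are not independent). With library totals only, 338 were lower and 220 higher. At 7 DAP 344 of them were tested, of which 119 were lower and 75 higher (two-sided Fisher's exact test, p = 0.00183). Of the 509 genes that fell more than 8-fold, 176 were higher and 169 lower at 7 DAP, where all 509 were tested (two-sided Fisher's exact test, p = 0.704). At 14 DAP 166 of them were tested, of which 65 were higher and 50 lower (two-sided Fisher's exact test, p = 0.16).

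Of the tested genes 71.1% differed between genotypes at 7 DAP and 63.8% at 14 DAP, and scaling by library composition is argued against as the cause, since the lowest count of calls under RLE factors, library totals or without the 20 most abundant genes was 99.9% of the reported count. An age offset along the change from 7 to 14 DAP is argued against as the whole cause, since the largest absolute correlation across genes between a genotype effect and a stage effect was 0.19 over 3 references at 2 stages. A few DNA segments carried with the edited allele would gather strong changes along the chromosomes, whose order the rows of the tables follow (142 of 142 adjacent microRNA precursors of a chromosome were in order, by positions in another build). The fullest 5% of windows of 250 tested genes held 9.11% of the 1219 changes beyond 2-fold at both stages, against a median of 8.53% in 1000 shuffles (permutation p = 0.0859). This argues against a few segments as the whole cause only. The fullest of 91 windows held 25 of these changes, against a mean of 13.4 per window, which the fullest exceeds by selection. MSH7 was not placed along the rows, so changes near it were not examined. Adjacent genes did change together, with a correlation of log2 fold changes between neighbouring rows of 0.088 at 7 DAP and 0.081 at 14 DAP (highest of 1000 shuffles 0.023 at 7 DAP), which fell to 0.009 and 0.003 at 5 rows apart. Age effects on transcripts that peak between these stages, DNA segments that hold a smaller part of the changes, many short or dispersed background differences, a difference in growth or handling shared by all libraries of a genotype, and an effect of the MSH7 mutation stay open.

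With 3 libraries against 3, the 10 possible splits are too few for a share under 0.05. The real split, 1 of 10, gave 17137 genes for genotype at 7 DAP and 15199 at 14 DAP, and in fits of 6 libraries 19963 for stage in wild type and 19574 in the mutant. The highest of the other splits gave 0 in each. Those splits mix the compared groups and so place their difference within groups, which by itself removes calls. The 0 therefore does not decide whether chance can be excluded.

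Zm00001d023265 was the only identifier with 0 counts in all 6 libraries of wild type and at least 10 in each of the 6 libraries of the mutant, and 0 identifiers showed the opposite. Reads moved between neighbouring gene models are argued against, since the adjacent identifiers lost 1.92% of the 32.2 CPM that it gained over both stages. The scarce identifier in the next row nevertheless lost most of its own counts, from 0.643 CPM in wild type to 0.026 CPM in the mutant. A DNA difference that also changes the neighbouring genes stays open, since the median absolute log2 fold change of the 10 rows on each side was at the 87.4th percentile of all such windows, with 10 of these neighbours tested. Sequence that differs between the parents of the lines, or that came with the editing construct, could also give such counts and was not tested.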
